A study of Escherichia coli K-12 with 4 samples.

How the data were processed

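The series holds 4 libraries, described as ChIP-exo per the labels, of Escherichia coli K-12 strain MG1655, a laboratory wild-type background. ChIP-exo is a chromatin immunoprecipitation in which exonucleases trim the precipitated DNA towards the edge of the cross-linked protein before sequencing. Per the labels' protocols, cells grew at 37 °C in M9 minimal medium with 0.2% glucose to an OD600 near 0.5, in 150 mL cultures inoculated at a dilution of 1/200. The labels put 2 libraries in the RpoD group (an antibody against RpoD, the primary sigma factor that directs RNA polymerase to most promoters) and 2 in the RpoB group (an antibody against RpoB, the beta subunit of core RNA polymerase). The protocol text in the same labels speaks of a myc-tag antibody, and the genotype field of the RpoD libraries gives a myc-tagged ArcA. The labels name no input or mock library.

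The deposited values are signal, the strand-specific read coverage at each base, in whole numbers and with no scaling found in them. Per the submitters' processing notes, bcl2fastq and Bowtie were used; their versions are not given in the sources used here. Per the reference names written in the files, the RpoD libraries lie on reference version 3 of the MG1655 chromosome (4641652 positions). The reference name of the RpoB libraries carries no version and their coverage spans 4639675 positions. Coordinates of different builds were not mixed or converted. The annotation at hand belongs to the version of the RpoD libraries (assembly ASM584v2, 4651 genes), so genes and coordinates are given for those libraries only, and no position was compared between the groups.

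The planned limma fits of RpoD against RpoB, the overlap of their regions and the shares of regions at leading-gene starts were therefore not run. The gene table also carries no strand. Transcription direction was taken only for 82 operons of textbook gene order, a list written after the reference and the annotation columns were known and before any gene value was seen. The track name written inside the data of the library labelled RpoD replicate 2 reads RpoB, against its label. Groups follow the labels, and the wording "the library labelled" is used for that reason. Separate cultures are described per the labels' protocols for each replicate, but the spread between libraries may still be partly technical.

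Reads have a fixed length of 51 bases in the RpoD libraries and 31 bases in the RpoB libraries, read from isolated runs of coverage. Read 5' ends were recovered from the coverage of each strand, and rebuilding coverage from them gave back every deposited value, with 0 negative counts. Reads per library were 16534921 and 15039565 for the libraries labelled RpoD and 5549296 and 5013221 for those labelled RpoB. Counting intervals below are 95% exact binomial (Clopper-Pearson) intervals. Amplified reads are not independent molecules, so these intervals cover counting error only. How reads of repeated sequence were placed is not given in the sources used here.

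Levels are the mean coverage of both strands over a gene or window, divided by the median of the library's 500-bp bins. Log2 values carry a pseudocount of 0.1 on that scale. Operon start windows ran from 250 bp upstream to 50 bp downstream of the first base of the first gene, and bodies from 200 bp downstream to the end of the last gene. A start was called occupied at a level of at least 3 in both libraries labelled RpoD. Enriched regions are 100-bp bins of at least 5 times the library's median 100-bp bin in both replicates of a group, merged when adjacent or 1 bin apart. Shares of regions were set against 100 circular shifts. Gene lists, 24 in number, were fixed before the data were examined. Of their symbols 3 were matched through synonyms and 0 stayed unmatched. A list's median was placed among 10000 random lists of the same size, for differences drawn from the 101 genes nearest in mean level. These random lists were not matched on operon or on position along the chromosome. Percentiles of lists whose genes share operons therefore overstate how unusual those lists are.

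The planned rule for named genes needed tests that were not run. In its place the text names genes from the 10 highest mean levels in the libraries labelled RpoD, the 10 largest differences between those libraries in each direction among genes at or above the median level, up to 4 members per list with the highest mean level, and rpoD, rpoB and arcA. Genes in repeated sequence (rRNA, identical tRNA lengths, insertion elements and similar pairs) and genes within 250 bp of one already taken were passed over in the first 2 parts. Operons, intergenic regions and enriched regions given as examples were chosen after their values were seen. With 1 library set against 1, no p-value was computed for genes. Measures that need no shared coordinates were compared between the groups with a two-sided exact permutation test, with no pairing, and Benjamini-Hochberg adjustment over 16 measures.

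The strand offset was planned as the lag, up to 300 bp, of the largest product of plus- and minus-strand coverage within enriched regions. Because coverage extends each read over its length, that lag is shorter than the distance between 5' ends, and a correlation of 5' ends up to 600 bp was added. The steps were tested on simulated data: 200 of 200 simulated peaks were found with 0 regions elsewhere, a strand offset of 180 bp was recovered as 180 bp from 5' ends and as 127 bp from coverage, and a log2 start-to-body difference of 2 was recovered as 1.97. Alternatives covered the log2 scale, bin size, threshold, overlap, capping at the 99.9th percentile, each 5' position counted once, molecules estimated from the share of occupied 5' positions, a replicate block with exact sign flips for the measures, division by a 200-kb running median, scaling to total signal, pseudocount, start window and thinning to 5013221 reads. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.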

Results

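The data cover 4 libraries, described in the labels as ChIP-exo, of E. coli K-12 MG1655 in mid-log growth on glucose minimal medium, 2 labelled RpoD (the primary sigma factor) and 2 labelled RpoB (the beta subunit of core RNA polymerase). The design names the mapping of sigma factor binding across the genome as the aim. The libraries labelled RpoD held 16534921 and 15039565 reads at 1001439 and 2232182 distinct 5' positions, or 16.5 and 6.74 reads per position. The libraries labelled RpoB held 5549296 and 5013221 reads at 1749800 and 1693193 distinct positions, or 3.17 and 2.96 reads per position. All levels are multiples of the library's median 500-bp bin. Coordinates are 1-based on NC_000913 version 3.

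The first question was where on the chromosome the signal of the libraries labelled RpoD lay. The highest mean level of an intergenic region outside repeated sequence was that between fhuF, which encodes a ferric reductase, and yjjZ (positions 4605664 to 4605803), at 108 in replicate 1 and 83.6 in replicate 2. The region between guaB, which encodes IMP dehydrogenase, and xseA (2634071 to 2634231) reached 163 and 22.3. The region upstream of rplK (4178289 to 4178446) reached 149 and 24.4, that upstream of csrB (2924525 to 2924734) 70.5 and 64.5, and that upstream of ilvL (3949970 to 3950321) 62.1 and 70.3. Among genes outside repeated sequence, ilvX, a short open reading frame behind the ilvL leader (3950507 to 3950557), had levels of 65.0 and 120. The small RNA gene csrB, a regulator of the CsrA protein (2924156 to 2924524), had 59.9 and 102, from 31037 and 51443 reads. The small RNA gene ryhB, which acts in iron limitation (3580922 to 3581016), had 62.1 and 46.5, and raiA, a ribosome-associated inhibitor (2737154 to 2737495), had 49.9 and 45.9.

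Bins at least 5 times the median in both libraries labelled RpoD formed 346 regions with a median width of 600 bp, which covered 4.53% of the chromosome. The number depended on the threshold, with 149 regions at 10 times the median and 565 at 3 times. Of the 346 regions, 317 (91.6%, 95% exact interval 88.2 to 94.3) reached an intergenic base, against a mean of 48.7% and a highest value of 56.4% in 100 circular shifts. When at least 50% of a region had to be intergenic the share was 31.5%, against 5.32% in shifts. Annotated intergenic sequence made up 10.7% of the chromosome and held 29.0% of the signal in replicate 1 and 20.2% in replicate 2. Intergenic regions of at least 100 bp, 1829 in number, had a median level of 2.16 in replicate 1 and 1.86 in replicate 2, against 1.03 and 1.01 for 3165 coding genes of at least 500 bp. The region with the highest mean level overlapped rimP, the initiator tRNA gene metY and argG (3317701 to 3318900), with 90.4 in replicate 1 and 41.8 in replicate 2. Because metY shares its length with other methionine tRNA genes, its part of that value is uncertain. Replicate 1 alone gave 574 regions, over 1.5 times the count in both libraries, and replicate 2 alone gave 427.

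Levels differed widely between gene lists fixed before the data were examined. The 11 leader peptide genes, most of them of attenuated biosynthetic operons, lie just behind their promoters. They had median levels of 17.5 in replicate 1 and 18.4 in replicate 2, both above all of 10000 random lists of that size. Of these leaders 8 had a level of at least 3 in both libraries, among them ilvL (60.5 and 95.3), leuL (59.4 and 63.7) and thrL (26.1 and 33.1). The 19 stable small RNA genes had medians of 8.51 and 5.37, also above all random lists. Of them, spf reached 50.72 and 30.04 and ssrS, the 6S RNA gene, reached 35.2 and 40.5. The 54 ribosomal protein genes had medians of 4.79 and 10.4, and 31 of them had at least 3 in both libraries.

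Other lists had low medians. The 29 class 1 and class 2 flagellar genes had median levels of 0.556 in replicate 1 and 0.264 in replicate 2, below all random lists, with 26 under 1 in both libraries. The 23 genes of the flagellar sigma factor had 0.625 and 0.280, and their highest member, the flagellin gene fliC, had 3.27 and 1.97. The 40 genes of alternative carbon catabolism had 0.784 and 0.428, at percentiles 0.05 and 0, with manX of the mannose transporter highest at 2.44 and 4.31. The 27 genes of the anaerobic respiration list, which also holds fermentation genes, had 0.623 and 0.649. Of its fermentation genes, focA (12.1 and 27.7) and adhE (3.38 and 27.0) stood far above that median. The 22 genes of the nitrogen sigma factor had 0.751 and 0.847, with glnA, the glutamine synthetase gene, at 2.91 and 6.08. The 5 genes of the iron citrate system had 0.727 and 0.711, at percentiles 6.14 and 17.67, and none reached 3 in either library. The 29 silent and prophage genes had 1.04 and 0.617, at percentiles 18.31 and 0.34, and 4 of them had at least 3 in both, among them essD (15.03 and 3.547). Low medians were not limited to such lists. The 24 genes of aerobic respiration had 0.744 in replicate 1 (percentile 0.06) and 1.77 in replicate 2 (percentile 92.83).

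**Figure D1:**
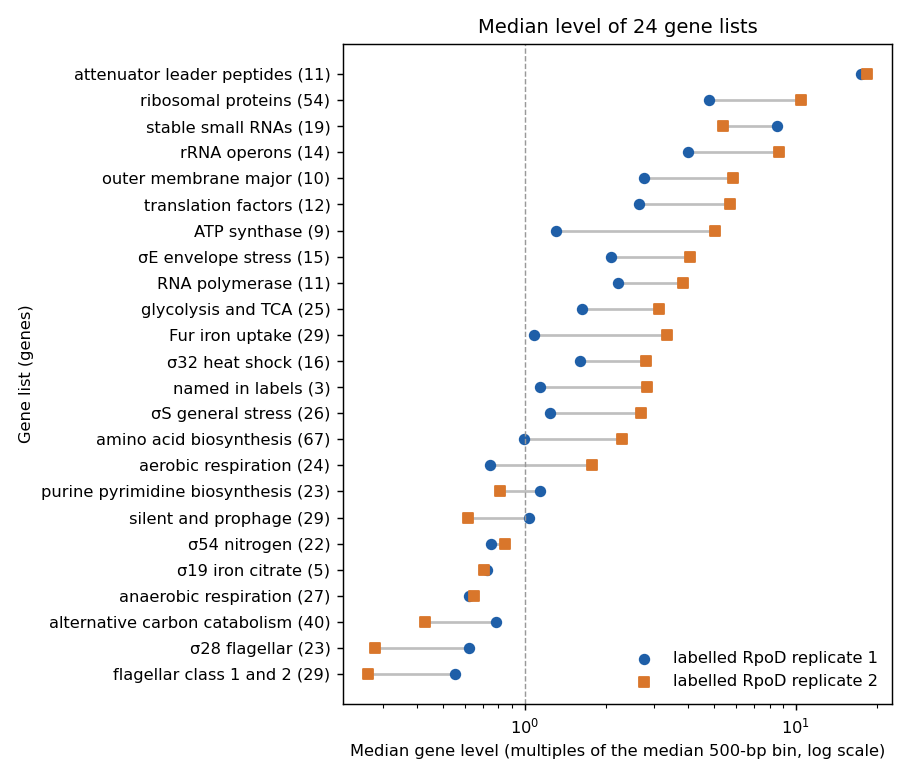
Median level of the genes of each list (horizontal axis, log scale, multiples of the median 500-bp bin) in the library labelled RpoD replicate 1 (circles) and replicate 2 (squares), with the number of genes in brackets and a dashed line at 1. Leader peptides stand highest at 17.5 and 18.4, and ATP synthase genes lie at 1.30 in replicate 1 and 5.04 in replicate 2.

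The next question was how far the 2 libraries labelled RpoD resembled each other, with 1 library on each side and so no replicate check. Of 82 operons of known gene order, the start window was higher in replicate 1 in 60 and the body higher in replicate 2 in 52. Of the 9 ATP synthase genes 8 were at least 2-fold higher in replicate 2, with medians of 1.30 in replicate 1 and 5.04 in replicate 2. Their median log2 difference, replicate 1 minus replicate 2, was -2.10, against 0.16 for random lists matched on level (percentile 0.01). With each 5' position counted once it was -1.21. The exception was atpI, the first gene of the operon, with 5.87 and 5.66, while atpH had 1.07 and 7.16. All 9 genes lie in that operon and are not independent, while the random lists were not matched on operon. The percentile therefore overstates how unusual this list is. The 54 ribosomal protein genes split by their place in the operon. Of 12 that come first in a listed operon 11 were higher in replicate 1, with a median log2 difference of 1.48, and of 32 later ones 28 were higher in replicate 2, with a median of -1.25. With each 5' position counted once these medians were 0.75 and -0.51, and 26 of the 32 later genes were higher in replicate 2. Over the 41 operons with an occupied start in both libraries, 19 first genes were higher in replicate 1 and 22 in replicate 2 (median -0.17), or 17 in replicate 2 with each position counted once (median 0.29). Of the 138 later genes of these operons 116 were higher in replicate 2 (median -1.38). Higher in replicate 1 were rplK (56.3 and 10.3), the first gene of its operon, and rpsQ (59.5 and 24.1), which lies beside the start of the rplN operon. As the last gene of the rpsJ operon, rpsQ was an exception among later genes. Higher in replicate 2 were rplO (1.41 and 18.5), rplR (1.62 and 13.7) and rpsK (1.86 and 19.6). In total 25 ribosomal protein genes were at least 2-fold higher in replicate 2 and 16 at least 2-fold higher in replicate 1. The median difference of the whole list was -0.86, and -0.06 with each 5' position counted once.

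Several other lists, most of them of housekeeping genes, went the same way. All but 1 of the 24 genes of aerobic respiration were higher in replicate 2, with a median difference of -1.17 against 0.19 for matched lists (percentile 0). The 24 genes come from the nuoA, cyoA, cydA and sdhC operons and so are not independent. Among them cydA, a cytochrome bd subunit, had 3.43 in replicate 1 and 14.4 in replicate 2. Of the 25 glycolysis and TCA cycle genes 21 were higher in replicate 2, with a median difference of -1.55 (matched lists 0.05, percentile 0), and gapA had 9.12 and 26.9. Of the 67 amino acid biosynthesis genes 50 were higher in replicate 2, with a median difference of -0.87 (matched lists 0.15, percentile 0). There the aspartokinase gene thrA had 3.24 and 14.8, while the leader thrL in front of it had 26.1 and 33.1. All 29 Fur-regulated iron uptake genes were higher in replicate 2 (median difference -0.89, matched lists 0.11, percentile 0.02), and exbD had 2.03 and 19.9. The leader peptides did not follow, with a median difference of -0.10 that changed sign under other settings. Among the 19 stable small RNA genes 13 were higher in replicate 1, but their median difference of 0.42 was ordinary for their level (matched lists 0.24, percentile 67). With each 5' position counted once the medians were -0.95 for aerobic respiration, -0.88 for glycolysis and TCA cycle, -0.59 for amino acid biosynthesis and -0.63 for iron uptake.

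Further lists had the following medians of the log2 difference, replicate 1 minus replicate 2. They were -1.23 for 10 major outer membrane proteins (matched lists 0.03), -0.89 for 16 heat-shock sigma factor genes (0.06), -1.09 for 15 envelope-stress sigma factor genes (0.19) and -0.52 for 26 general-stress sigma factor genes (0.23). The difference was -0.82 for the RNA polymerase list, 11 genes of polymerase subunits and of elongation and termination factors (matched lists 0.04). It was -0.77 for 12 translation factor genes (0.39). The 14 rRNA genes gave -1.49, but how reads of their copies were placed is not given in the sources used here, and the value became 0.38 when each 5' position was counted once. That setting also gave -0.68 for outer membrane proteins, -0.66 for heat shock, -0.47 for envelope stress, -0.41 for general stress, -0.57 for RNA polymerase and -0.19 for translation factors. The 29 silent and prophage genes gave 0.92 (matched lists 0.46, percentile 99.98), and the 23 purine and pyrimidine genes gave 0.20 (0.34). Medians were also positive for class 1 and class 2 flagellar genes (0.83, matched lists 0.80) and flagellar sigma factor genes (0.70, matched lists 0.75). The same held for alternative carbon catabolism (0.78, 0.63), anaerobic respiration (0.42, 0.69) and the nitrogen sigma factor (0.17, 0.53). The iron citrate list gave -0.13 (0.56). Over all 4651 genes the median difference was 0.36, and scaling to total signal instead of the median bin lowered it to 0.22. The matched lists were not matched on position along the chromosome. Along it, the 200-kb running median had a highest over lowest value of 1.87 in replicate 1 and 4.16 in replicate 2. Position may therefore add to the difference of a list.

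Among single genes at or above the median level, the lowest differences, replicate 1 minus replicate 2, belonged to gatZ, a galactitol catabolism gene (-3.88, levels 2.12 and 32.6, positions 2175059 to 2176321), hisD of histidine synthesis (-3.67, levels 0.849 and 11.95, positions 2091097 to 2092401) and rplO (-3.63). The highest belonged to ydfT (2.59, levels 13.2 and 2.12, positions 1642489 to 1643241), guaB (2.54, levels 16.7 and 2.79, positions 2632604 to 2634070) and agaB (2.498, levels 3.27 and 0.497). Counting error on these log2 values was at most 0.16 in either direction. With each 5' position counted once the differences shrank and changed order, to -1.26 for gatZ, -2.32 for hisD, -1.61 for rplO, 1.71 for ydfT, 1.30 for guaB and 1.94 for agaB. Of the genes the labels name, rpoD had levels of 0.830 and 2.33, rpoB 1.14 and 2.82, and arcA 2.37 and 4.81.

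**Figure D2:**
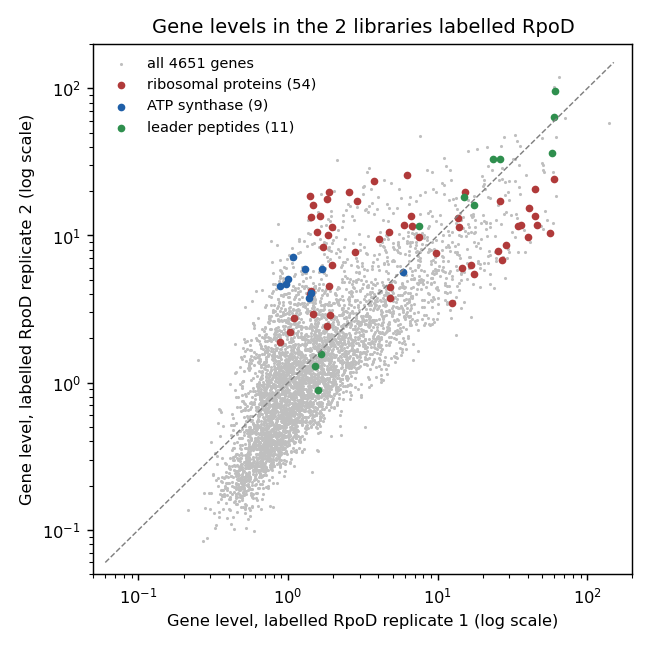
Level of each of 4651 genes in the library labelled RpoD replicate 1 (horizontal) and replicate 2 (vertical), both on log scales in multiples of the median 500-bp bin, with a dashed line of equality. The 9 ATP synthase genes sit above the line except atpI (5.87 and 5.66), and ribosomal protein genes lie on both sides.

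Operons of known gene order located this difference. In 41 operons with an occupied start in both libraries labelled RpoD, the median start level was 18.6 in replicate 1 and 10.4 in replicate 2, and the median body level was 1.68 and 4.44. The median log2 ratio of start to body was 3.04 in replicate 1 (bootstrap 95% interval over operons 2.59 to 3.45) and 1.14 in replicate 2 (0.92 to 1.59). The ratio was higher in replicate 1 in 40 of the 41, with a median difference of 1.66 (1.40 to 2.07). The exception was the secE-nusG operon, whose body lies beside the rplK promoter. In the rplN operon, which encodes ribosomal proteins, the start had 74.4 and 27.4 and the body 4.77 and 15.3. In the thrL operon of threonine synthesis the start had 27.6 and 23.7 and the body 1.956 and 11.6. In the atpI operon of ATP synthase the start had 8.88 and 5.17 and the body 1.22 and 5.05. In the gltB operon of glutamate synthesis the start had 23.1 and 18.2 and the body 1.17 and 6.001.

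Over all 82 operons the median log2 ratio was 1.88 in replicate 1 (1.40 to 2.41) and 0.84 in replicate 2 (0.58 to 1.03), and the ratio was higher in replicate 1 in 64 of them. The median difference of 1.05 had a bootstrap interval of 0.74 to 1.56. In the other 41 operons it was 0.31 with an interval of -0.14 to 0.87, which includes 0. These spanned a wide range, from -2.41 for prpB through -0.71 for lacZ and 0.31 for flgB to 2.97 for cyoA and 3.35 for cysD. Operons are not replicates, and these intervals describe the spread over operons in 1 pair of libraries.

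**Figure D3:**
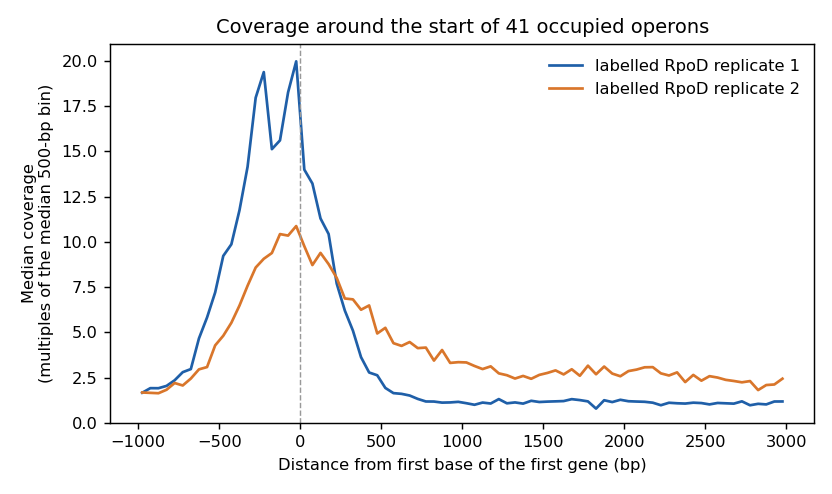
Median coverage of 41 operons with occupied starts (vertical axis, multiples of the median 500-bp bin) in 50-bp steps around the first base of the first gene (horizontal axis, bp), in the libraries labelled RpoD replicate 1 (blue) and replicate 2 (orange). Just upstream of the first base the medians are 19.98 and 10.9, and 2000 bp downstream they are 1.19 and 2.86. Some of the 41 operons, such as the rpmH operon (3884336 to 3884852), end before that distance.

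The widths of enriched stretches differed in the same direction. The library labelled RpoD replicate 2 had 36 regions of at least 2500 bp, a limit chosen after the values were seen, and replicate 1 had 2. The contrast was smaller at 1000 bp, with 146 and 132 regions, and the median widths were 700 and 600 bp. The widest in replicate 2 ran over 11100 bp from yhdN to rplB (3439501 to 3450600), across 25 genes that include the rpsM and rplN operons of ribosomal proteins, where the mean level was 7.45 in replicate 1 and 14.7 in replicate 2. A region of 5100 bp covered thrL to thrC (1 to 5100), with 4.07 and 12.99. The widest in replicate 1 ran over 3600 bp from tufB to rplJ (4176801 to 4180400), with 45.9 and 14.5. Of the 574 regions of replicate 1, 334 (58.2%, exact interval 54.03 to 62.26) overlapped a region of replicate 2, against a mean of 14.3% in 100 shifts. Of the 427 regions of replicate 2, 318 (74.5%, 70.1 to 78.5) overlapped one of replicate 1, against 18.1%.

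Across 500-bp bins of coverage the libraries labelled RpoD correlated with Pearson's r = 0.65 and Spearman's rho = 0.71, and those labelled RpoB with 0.999 and 0.994. Bins are not independent replicates, and no p-value is given. For read counts per bin the chi-square per degree of freedom was 517 between the libraries labelled RpoD and 1.70 between those labelled RpoB, the latter above the value of 1 for sampling noise alone. Separate amplifications of one sample would also exceed that value, so separate cultures rest on the labels, which give 2 samples, and SDs of that pair may be technical.

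The last comparison set the libraries labelled RpoD against those labelled RpoB in measures that need no shared coordinates. Because the track name of RpoD replicate 2 reads RpoB, means and SDs of the RpoD group may mix different immunoprecipitations. Signal of the libraries labelled RpoB fell into more and narrower regions. They had 1825 ± 29.7 enriched regions each (SD, n = 2) with a median width of 300 ± 0 bp, against 501 ± 104 regions of 650 ± 70.7 bp in the libraries labelled RpoD. Those regions covered 17.3 ± 0.358% of the chromosome in the RpoB libraries and 8.43 ± 0.682% in the RpoD libraries. The correlation between neighbouring 500-bp bins was 0.298 in both libraries labelled RpoB, and 0.524 and 0.744 in those labelled RpoD. At 2 kb apart it was 0.0144 in RpoD replicate 1 and 0.176 in RpoD replicate 2, and 0.0157 and 0.0152 in the RpoB libraries, so that the groups overlapped. The share of read 5' ends in the top 1% of bins was 16.4 ± 3.53% for RpoD and 15.1 ± 0.200% for RpoB, a difference within the spread.

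The distance between strands separated the groups. Plus- and minus-strand 5' ends of the libraries labelled RpoD correlated best at a lag of 352 bp in replicate 1 and 394 bp in replicate 2, with no peak under 100 bp. In the libraries labelled RpoB the best lags were 48 bp in replicate 1 and 33 bp in replicate 2, but both libraries had nearly equal peaks at both lags. At 33 and 48 bp r was 0.3173 and 0.3173 in replicate 1, and 0.311 and 0.309 in replicate 2. The planned coverage product peaked at 11 bp in both RpoB libraries and at 297 and 300 bp in the RpoD libraries, the latter at or near the limit of 300 bp. Of 16 measures, several of which describe the same regions or the same lag, 11 had both RpoD values on one side of both RpoB values. Each of these had p = 0.333 in a two-sided exact permutation test (n = 2 per group; adjusted p = 0.485), the smallest p that 2 against 2 allows. Read length and reference differed with the group.

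**Figure D4:**
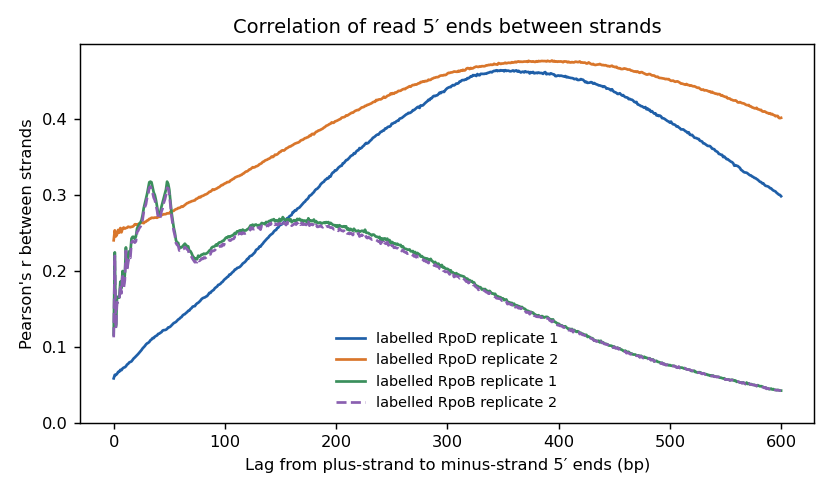
Pearson's r between plus-strand and minus-strand read 5' ends (vertical axis) against the lag between them in bp (horizontal axis), for each of the 4 libraries. The libraries labelled RpoB peak at 33 and 48 bp and again more broadly, and the libraries labelled RpoD rise to 352 and 394 bp.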

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

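Alternatives to the replicate correlation on the log2 scale and in 100-bp bins, and capping of the strand offset, were planned; all others were chosen after seeing the data. The planned gene fits, with and without a replicate block, and region overlaps between groups were not run, since the groups lie on different references. For the 16 measures that need no coordinates, a replicate block with exact sign flips gave a smallest p of 0.5, the smallest that 2 pairs allow, against 0.333 without it; 11 measures had one sign in both pairs. The labels tie no replicate numbers across groups.

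For the RpoD pair, r = 0.65 became 0.73 on the log2 scale, 0.71 with each 5' position counted once, 0.68 with molecules estimated from occupied positions, 0.67 with capped values and 0.63 after division by the 200-kb running median. For the RpoB pair, 0.9987 became 0.9956 (log2), 0.9977 (100-bp bins), 0.9965 (each position once), 0.9988 (capped) and 0.9981 (running median). The coverage-product offset of RpoD replicate 1 moved from 297 to 300 bp with capped values; from 5' ends the 4 offsets were 352, 394, 48 and 33 bp. The 346 shared RpoD regions became 149 at a threshold of 10 and 565 at 3, and ranged from 427 to 574 with 1 replicate left out; the 1786 RpoB regions became 1248 at a threshold of 10 and 2087 at 3, and ranged from 1804 to 1846 with 1 replicate left out. The share of RpoD regions reaching an intergenic base was 31.5% when 50% of the region had to be intergenic (5.32% in shifts), and ranged from 84.1% to 88.9% with 1 replicate left out. The overlap of replicate 1 regions with replicate 2 was 47.9% at a threshold of 10 and 48.4% with 50% of the region shared. The median operon difference of 1.05 was 1.66 in operons with occupied starts, and lay between 0.98 and 1.42 in the other settings.

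Sign changes between the RpoD libraries appeared in 2 lists. The rRNA genes went from -1.49 to 0.38 with each 5' position counted once. The leader peptides went from -0.10 to 0.12 with capped values, 0.70 with each position counted once and 0.054 after the running median. Causes were not tested. Of the further values for single genes, lists and bins, 117 stayed within their spread and 107 moved by more with the direction kept. Thinned to 5013221 reads the RpoD pair again gave 346 regions.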

Other observations

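Classes of gene other than the lists differed in level. The 86 tRNA genes had median levels of 10.6 in the library labelled RpoD replicate 1 and 11.8 in replicate 2, the 107 noncoding RNA genes 3.49 and 3.56, and the 4290 coding genes 1.15 and 1.16. The transfer-messenger RNA gene ssrA had 35.1 and 30.01. Of the 346 shared regions 29 held no intergenic base, among them one of 700 bp inside nlpD (2867701 to 2868400), with levels of 12.7 and 10.1, and one of 600 bp inside pyrG (2908501 to 2909100), with 11.1 and 11.4.

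Among rRNA genes, rrsG and rrsD had levels of 19.9 and 26.9 in replicate 1 and 21.7 and 24.1 in replicate 2, while the other copies of rrs had 4.33 to 6.69 and 8.51 to 8.998. How reads of identical copies were placed is not given in the sources used here. Of the distinct 5' positions in RpoB replicate 1, 53.4% were also occupied in RpoB replicate 2, and of those in replicate 2 55.2% in replicate 1. Of those in RpoD replicate 1 45.8% were also occupied in RpoD replicate 2, and of those in replicate 2 20.5% in replicate 1.

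The tests on operons with occupied starts, on estimated molecules, on the lag between strands and on the ends of arcA were chosen after the results were seen. Predictions for the other tests were written before their results, although the settings of counting each 5' position once and of the 200-kb running median were added after the data were first examined.

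The first pattern weighed is the difference between the 2 libraries labelled RpoD, with higher start-to-body ratios in replicate 1. A slope from replication origin to terminus does not account for the low correlation of the 2 libraries, since r was 0.63 after division by the 200-kb running median. That running median did differ in range between them. Its highest over lowest value was 1.87 in replicate 1 and 4.16 in replicate 2, against 2.44 and 2.41 in the libraries labelled RpoB. Few distinct molecules in replicate 1 do not account for all of the difference. With each 5' position counted once r was 0.71, and with molecules estimated from the share of occupied positions it was 0.68. Those shares were 71.4% in shared regions and 24.05% on the chromosome in replicate 2, and 47.8% and 10.8% in replicate 1. On that estimate the median difference in operons with occupied starts was 1.35 (1.17 to 1.78), against 1.66 without it. Few molecules may still add to the difference. The lowest and highest single-gene differences named above shrank with each position counted once. That setting compresses high levels and those genes were picked as extremes, so their shrinkage cannot show few molecules. A candidate explanation is that the library labelled RpoD replicate 2 holds core polymerase, as its track name reads: over all 82 operons the median difference was 1.05, over the 0.5 set beforehand, but its sign held in 78.0% against the 80% required, while in the 41 operons with occupied starts it was 1.66 with 97.6% of one sign. The label stays open. The regions of RpoD replicate 2 alone reached an intergenic base in 84.1%, against 55.2% in shifts, and those of replicate 1 alone in 88.9%, against 49.7%. This share cannot decide the label, since no library labelled RpoB was placed on genes to give the value for core polymerase. The narrower regions of the libraries labelled RpoB cannot serve as a reference either, since read length and strand lag also differed. A difference in growth between the cultures was not tested.

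The second pattern is the narrower enriched stretches of the libraries labelled RpoB. Their lower depth does not account for it, since the lowest correlation of neighbouring bins in a library labelled RpoD was 0.523 after thinning to 5013221 reads, against 0.298 in those labelled RpoB. The strand lag of at least 352 bp in the libraries labelled RpoD, with no peak under 100 bp, is consistent with read ends at the ends of sheared fragments and not at the edge of the protein, so that these libraries may not have been trimmed as ChIP-exo libraries are. As both libraries labelled RpoD share read length and reference, the protein, the trimming and the sequencing run remain confounded, and a biological difference between sigma factor and core polymerase stays open.

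The third pattern concerns the genotype label of the libraries labelled RpoD, which gives a myc-tagged ArcA. A tag inserted at an end of arcA (4639590 to 4640306) would remove the reads that run across that junction of the reference. Within 6 bp of the lower-coordinate end at least 46 reads in replicate 1 and 173 in replicate 2 crossed with 8 or more bases on each side, against medians of 54 and 161 at 60 to 300 bp away. At the other end they were 302 and 347, against 316 and 290, and within 30 bp of the lower-coordinate end the fewest were 20 and 127 (medians 67 and 209). The lowest ratio within 6 bp, 0.852, argues against an insertion at the annotated ends in most of the sequenced cells, although the dip to 20 reads nearby is unexplained, 13.3% and 27.6% of the flanking positions of that end in replicates 1 and 2, and 18.3% and 0% of those of the other end, lay under 0.5 of their median, and a smaller share of tagged cells was not tested.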
